A study of Arabidopsis thaliana with 12 samples.

How the data were processed

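The deposited table holds gene counts for 12 libraries, and its unit is the count, per the file headers and the submitters' processing notes. Per those notes, reads were called with bcl2fastq 2.19, trimmed with fastp 0.12.4 and aligned to TAIR10 with STAR 2.7.9a. Per the labels' protocols, seeds came from plants in long days (16 h light and 8 h dark), were kept in RNAlater after dissection and gave stranded poly(A) libraries with molecular-identifier adaptors. Whether reads were deduplicated by those identifiers is not given in the sources used here. The combined table was checked against the per-library STAR files and equals their reverse-strand column in all 12. It has 32833 gene entries after 4 summary entries were removed, 32548 of them in the reference annotation (TAIR10.1, used here for names, exon lengths and neighbours only, since the counts are on TAIR10) and 10804 with a symbol other than the locus name.

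Between 1.95% and 7.91% of reads were unmapped and 2.61% to 4.36% mapped to several places. Reads on no annotated exon of the counted strand made up 3.53 ± 0.147% in Col-0 embryo and 2.26 ± 0.230% in mutant embryo. In the seed coat they made up 2.16 ± 0.0879% in Col-0 and 1.66 ± 0.133% in the mutant. Plastid genes took 0.141 ± 0.0249% and 0.0871 ± 0.00516% of reads in the embryo of Col-0 and mutant, and 0.0890 ± 0.0189% and 0.0520 ± 0.00885% in the seed coat. The share of strand-assigned reads on the reverse strand was 94.4% to 96.4%, and 18600 to 19676 genes had reads in each library. Gene reads ranged from 14003564 to 15047509 in Col-0 embryo, 13927944 to 17619031 in mutant embryo, 10301817 to 14947969 in Col-0 seed coat and 13685009 to 15923520 in mutant seed coat.

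Genes were tested with edgeR 4.0.16 (quasi-likelihood F test) in R 4.3.3. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM and the 4 group means were fitted in 1 model of all 12 libraries, with a common biological coefficient of variation of 0.166. Mean TMM factors were 1.32 in Col-0 embryo, 1.03 in mutant embryo, 0.950 in Col-0 seed coat and 0.776 in mutant seed coat. Contrasts were mutant against Col-0 in the embryo, the same in the seed coat, the difference of these 2 effects, and seed coat against embryo in Col-0. Calls used a Benjamini-Hochberg adjusted p under 0.05. CPM values use the TMM-scaled library sizes. Where a group had 0 reads, the fold is given against a floor of 3 reads per library, and with 1 to 3 reads as a ratio of counts with its 95% counting interval.

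The 17 gene lists and 3 marker lists (322 entries) and the rule for naming genes were written before the data were examined. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with prior count 2), and p was adjusted over the lists within each comparison; the alternatives were an estimated correlation and fry. Members were counted as higher, lower or not called over all genes and again with p adjusted over the list alone. Counts are out of the members with enough reads to be tested. These were 15 of 25 photosynthesis genes, 9 of 16 cell wall enzymes, 7 of 16 DNA replication genes and 3 of 11 endosperm markers. A gene near the filter could pass through the group where it was high. Named genes are the family of the targeted genes, the 6 largest changes each way per tissue among called genes with a symbol, at least 5 CPM in a group and replicates that did not overlap, up to 3 members with the smallest p per list, the 4 smallest p each way for the difference, and the 5 largest each way for tissue. Some further well-known list members are named with their values, and 1 gene that met the rule is not reported here.

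Replicate numbers were checked for pairing by correlating each library's deviations from its group means. Embryo and seed coat of the same genotype and number correlated at 0.40, 0.46 and 0.27 in Col-0 and 0.40, 0.51 and 0.16 in the mutant, so the number was taken to mark a seed lot split into tissues, although the mutant embryo library numbered 3 correlated more with mutant seed coat 1 (0.22). A model with the seed lot as a block was therefore added after the data were seen for the difference and the tissue comparison.

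The workflow was tested on simulated data made with the observed overall mean of each gene and the trended spread, with few genes changed. In the embryo contrast it recovered 29.2% of 1.5-fold, 69.4% of 2-fold, 93.9% of 4-fold and 100% of 8-fold changes. In the contrast for the difference it recovered 4%, 26%, 74% and 94% of them, and false calls made up 4.70% to 7.43% of calls over the contrasts. Calls there numbered 104 to 153 per contrast, beside 7610 in the real embryo contrast and 932 for the real difference. The threshold on p was thus looser in the real data, and these rates need not hold for it.

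Alternatives tried were RLE size factors, scaling without the storage, oil body and LEA lists, no low-count filter, unstranded counts, DESeq2 1.42.0, a 2-fold threshold, the replicate number as a block, each library left out in turn and only the 6 libraries of a comparison. Added after seeing the data were scaling by total reads only, the seed lot block and leaving out both mutant libraries numbered 2, which stood apart on the third principal component (36.95 in the embryo and 36.47 in the seed coat, against -27.10 to -3.85 in the other mutant libraries). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.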

Results

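RNA was sequenced from dissected mature seeds of Arabidopsis thaliana, comparing the wild type Col-0 with the double mutant Atsdr4l-5 dig2. Seeds were taken about 18 days after pollination, kept at room temperature for a further 2 days, then imbibed for 1 to 2 h before the embryo was parted from the seed coat, which carries the endosperm. The 4 groups, Col-0 embryo, mutant embryo, Col-0 seed coat and mutant seed coat, had 3 biological replicates each, 12 libraries in all. Libraries held 10301817 to 17619031 reads on genes, and 16238 genes had enough reads to be tested. Expression is given as CPM (counts scaled to library size) as mean ± SD with n = 3, changes as log2 fold change with an adjusted p, and a gene is said to rise or fall only when its adjusted p was under 0.05. Libraries of the same group correlated at 0.973 to 0.991 and libraries of different groups at no more than 0.927. The first principal component held 48.7% of the variance and the second 34.0%, and together they parted tissue and genotype.

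**Figure D1:**
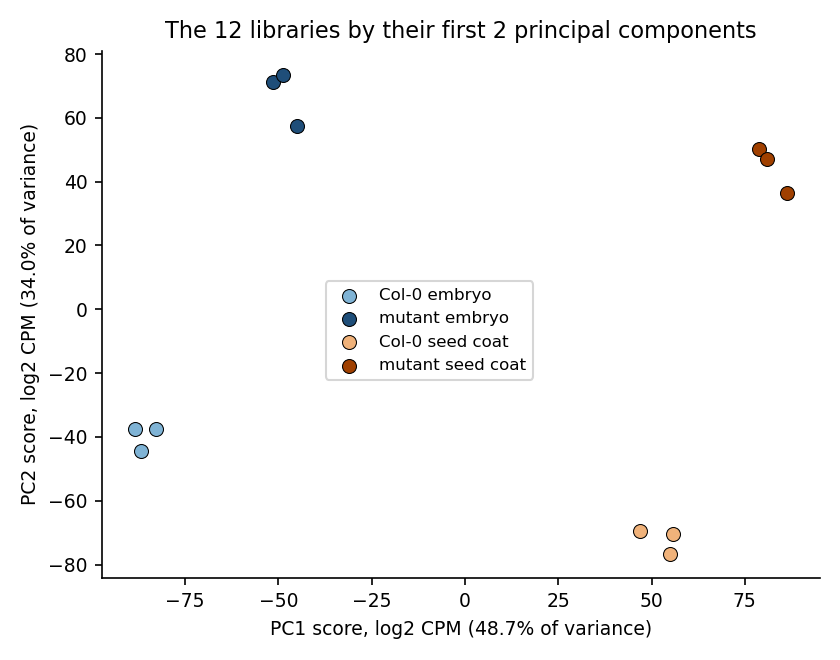
Principal components of the 12 libraries on log2 CPM, with component 1 (48.7% of the variance) on the horizontal axis and component 2 (34.0%) on the vertical axis. Each point is 1 library, coloured by group, and the 4 groups lie apart.

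The mutated genes are named for a small family of plant transcriptional repressors known as AITR, SDR4-like or DIG proteins, which act in abscisic acid responses and seed dormancy. DIG2 (AT5G50360) kept its reads in the mutant, at 133 ± 59.2 CPM in Col-0 embryo and 135 ± 16.6 CPM in mutant embryo (log2 0.01, adjusted p = 0.977). In the seed coat DIG2 stood at 161 ± 50.8 CPM in Col-0 and 142 ± 31.7 CPM in the mutant (log2 -0.17, adjusted p = 0.669). The type of lesion in dig2 is not given in the sources used here, and the reference names 0 loci as SDR4-like or ODR1, so AtSDR4L itself was not identified. Of the 6 family members with enough reads, 5 rose and 0 fell in each tissue, DIG2 being the sixth. AT5G63350 rose from 44.8 ± 22.6 to 220 ± 38.0 CPM in the embryo (adjusted p = 0.00011) and from 79.8 ± 20.5 to 378 ± 77.8 CPM in the seed coat (log2 2.25). AT3G48510, also known as DIG1, rose with log2 2.63 in the embryo and 2.44 in the seed coat, and AT5G40800 rose from 0.236 ± 0.163 to 9.23 ± 1.21 CPM in the embryo (log2 5.29) and with log2 4.43 in the seed coat. AT5G38300 rose with log2 1.94 in the embryo. AT3G27250 had 0 reads in Col-0 and 53 in the mutant embryo, at least 6.70-fold higher. In the seed coat the rise of AT5G38300 (log2 1.25, adjusted p = 0.0437) and that of AT3G27250 (4 reads in the mutant, adjusted p = 0.0316) were lost when most single libraries were left out, for AT5G38300 with log2 0.73 without the mutant seed coat library numbered 3. AT5G40790 had too few reads to be tested. As a list the family was higher by camera in the embryo (adjusted p = 0.00198; adjusted p = 0.183 with an estimated correlation) and in the seed coat (adjusted p = 0.0185; adjusted p = 0.288 with an estimated correlation), with 5 higher in each tissue when adjusted over the list alone.

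The mutant embryo carried more of many transcripts of late seed maturation. DOG1, a dormancy gene, rose, as did 24 of 27 LEA proteins and dehydrins, 7 of 8 oil body proteins, 10 of 17 abscisic acid signalling genes and 10 of 15 photosynthesis genes, while 8 of 14 genes that turn stored oil into sugar and 7 of 11 embryo markers fell. These lists were called by camera with the preset correlation, and every call was lost with an estimated correlation (adjusted p = 0.249 for oil body proteins and 0.183 for the others). Of the genes tested, 4129 rose and 3481 fell, 7610 in all or 46.9%, and 1730 of those rose and 1274 fell by at least 2-fold. Scaled by total reads only, 2296 rose and 6882 fell. The replicates of the 2 genotypes did not overlap for 57.3% of genes, beside 10% by chance. With total reads only, the median of all genes shifted by -0.35 in the embryo, -0.29 in the seed coat and -0.47 between the tissues of Col-0, so every change here is relative to the bulk of genes.

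DOG1, the main quantitative regulator of seed dormancy, rose from 21.4 ± 5.97 to 182 ± 14.3 CPM in the mutant embryo (log2 3.09, adjusted p = 1.4e-06). Among dormancy regulators, 6 rose, 6 fell and 5 were not called. The counts were the same over the list alone, and camera found no common direction (adjusted p = 0.662). Under total reads only 5 rose and 10 fell. E12A11, better known as MFT, which feeds back on abscisic acid signalling in germinating seeds, rose with log2 1.01, and AIL5, an AP2 factor of abscisic acid responses in seeds, rose with log2 0.79. PIL5 (PIF1), a repressor of germination in the dark, fell with log2 -1.46, and RVE2, which promotes dormancy, fell with log2 -0.85. Of 15 seed maturation regulators, 10 rose, 0 fell and 5 were not called (camera adjusted p = 0.00697; adjusted p = 0.183 with an estimated correlation; 10 higher over the list alone; 7 higher and 2 lower with total reads only). ABI3, a master regulator of maturation, rose from 140 ± 14.9 to 368 ± 45.6 CPM (adjusted p = 2e-06), FUS3 from 2.58 ± 0.682 to 23.9 ± 2.53 CPM (log2 3.20) and ABI5 with log2 0.95. BBM, an AP2 factor of embryo identity, rose from 8.31 ± 0.670 to 31.4 ± 2.52 CPM (log2 1.92). LEC1 and LEC2, which start the maturation phase, had too few reads to be tested. Of 12 repressors of that program, 2 rose, 4 fell and 6 were not called (camera adjusted p = 0.465; 2 higher and 4 lower over the list alone; 1 higher and 7 lower with total reads only). HSI2 (VAL1), which silences maturation genes after germination, fell with log2 -0.42 and VRN2, a Polycomb subunit, rose with log2 1.51.

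LEA proteins and dehydrins, which protect cells in the dry state, had the smallest camera p of the lists: 24 of 27 rose, 0 fell and 3 were not called, with a median of 2.63-fold (camera adjusted p = 2.47e-10; adjusted p = 0.183 with an estimated correlation; 24 higher over the list alone). The dehydrin ERD10 had 0 reads in the 3 Col-0 embryo libraries and 359 ± 32.1 CPM in the mutant, at least 2272-fold higher. COR47, another dehydrin of cold and drought responses, went from 1 read in Col-0 to 951 reads, a ratio of 1091 with a 95% counting interval from 195 to 43128. LEA7 rose from 440 ± 78.9 to 4945 ± 508 CPM (log2 3.49) and RAB18 with log2 0.97. The list took up 8.27% of gene reads in Col-0 embryo and 13.5% in mutant embryo. Oil body proteins coat the seed's oil droplets, and 7 of 8 rose, 0 fell and 1 was not called (camera adjusted p = 0.000426; adjusted p = 0.249 with an estimated correlation; 8 higher over the list alone). OLEO1 went from 7456 ± 1017 to 19945 ± 1412 CPM (log2 1.42). Seed storage proteins split: 6 rose, 3 fell and 3 were not called, the same over the list alone, with no common direction (camera adjusted p = 0.364; 6 higher and 6 lower with total reads only). The 2S albumin SESA1 rose from 61.1 ± 12.2 to 650 ± 19.8 CPM (log2 3.41), whereas the cruciferin CRU2 (log2 -1.25), the albumin SESA5 (log2 -0.83) and the vicilin PAP85 (log2 -0.59) fell. The list took up 11.2% of gene reads in Col-0 embryo and 6.85% in mutant embryo.

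Abscisic acid signalling had 10 of 17 members higher, 3 lower and 4 not called (camera adjusted p = 0.00898; adjusted p = 0.183 with an estimated correlation; 11 higher and 3 lower over the list alone). The transcription factor ABF2 rose from 2.56 ± 0.390 to 26.5 ± 2.72 CPM (log2 3.37), and the phosphatases HAI3 (21.7 ± 3.26 to 112 ± 25.2 CPM, log2 2.38) and AHG1 (log2 1.98), which restrain the pathway, rose with it. The receptors PYR1 (log2 -2.02) and PYL1 (log2 -1.55) and the phosphatase ABI1 (log2 -1.06) fell. PYL4, a further receptor outside the list, fell from 15.2 ± 10.6 to 0.311 ± 0.186 CPM (log2 -5.54). In abscisic acid metabolism 6 of 12 rose, 1 fell and 5 were not called, the same over the list alone (camera adjusted p = 0.0631). NCED6, a synthesis gene usually read in the endosperm, rose from 0.708 ± 0.328 to 20.8 ± 4.92 CPM (log2 4.88) and its relative NCED5 fell (log2 -1.69). CYP707A2, which degrades the hormone on imbibition, rose with log2 1.20. In gibberellin metabolism and signalling 8 of 16 rose, 4 fell and 4 were not called (camera adjusted p = 0.449; 8 higher and 5 lower over the list alone; its median turned to -0.12 with total reads only). GA2OX6, which inactivates gibberellin, rose from 1.71 ± 0.824 to 13.0 ± 2.73 CPM (log2 2.90), while GA20OX2, which makes it, went from 53 reads to 0, at least 5.20-fold lower.

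Genes of photosynthesis rose from very low levels, 10 of 15 higher, 2 lower and 3 not called, with a median log2 of 2.01 (camera adjusted p = 0.00198; adjusted p = 0.183 with an estimated correlation; 10 higher and 2 lower over the list alone). RCA, the activase of Rubisco, rose from 7.81 ± 1.61 to 143 ± 8.51 CPM (adjusted p = 1.7e-09) and the oxygen-evolving subunit PSBO1 with log2 3.79. The Rubisco subunit RBCS1A (log2 -0.68) and the photosystem subunit PSAF (log2 -1.70) fell. Oil breakdown and the glyoxylate cycle fell in 8 of 14 members, with 1 higher and 5 not called (camera adjusted p = 0.00198; adjusted p = 0.183 with an estimated correlation; 1 higher and 8 lower over the list alone; 13 lower with total reads only). PCK1, which feeds new sugar synthesis, fell from 1269 ± 140 to 319 ± 41.9 CPM (log2 -1.99) and the oxidation enzyme MFP2 with log2 -1.38. ACX2, an oxidase of the same route, rose with log2 0.25, a call lost with RLE size factors and with total reads only. In fatty acid and oil synthesis 5 rose, 5 fell and 5 were not called, the same over the list alone (camera adjusted p = 0.584; with total reads only 3 rose and 8 fell and its median turned to -0.34). The desaturase SSI2 rose with log2 1.58 and the desaturase FAD2 fell with log2 -1.28.

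All 3 tested genes of raffinose family sugar synthesis rose, GolS2 from 130 ± 41.2 to 519 ± 67.2 CPM (log2 2.00), with 3 higher over the list alone (camera adjusted p = 0.02; adjusted p = 0.183 with an estimated correlation). Heat shock proteins and factors rose in 7 of 15 members, fell in 2 and were not called in 6 (camera adjusted p = 0.0358; adjusted p = 0.526 with an estimated correlation; 8 higher and 2 lower over the list alone), and with total reads only 4 rose and 3 fell. HSP70 rose with log2 1.16 and HSP18.2 fell with log2 -0.97. This list call was lost without the first Col-0 embryo library (adjusted p = 0.0892) or without the second (0.0529) or last (0.0601) mutant embryo library. DNA replication and cell cycle genes fell in 4 of 7 tested members, 3 not called (camera adjusted p = 0.0358; adjusted p = 0.183 with an estimated correlation; 4 lower over the list alone), with CDKB2;1 at log2 -1.62. That call was lost without the first Col-0 embryo library (adjusted p = 0.0734) or the second mutant embryo library (0.0586). Cell wall loosening enzymes had 1 higher, 4 lower and 4 not called, the same over the list alone (camera adjusted p = 0.364), with the mannanase MAN7 higher (log2 1.93) and the expansin EXP3 lower (log2 -2.61). Embryo markers fell in 7 of 11 members with 1 higher and 3 not called (camera adjusted p = 0.00697; adjusted p = 0.183 with an estimated correlation; 1 higher and 8 lower over the list alone). The homeodomain leucine zipper factor REV fell from 11.4 ± 1.71 to 4.96 ± 0.566 CPM (log2 -1.20) and the root factor SCR with log2 -1.15, while WOX2, an early embryo factor, rose with log2 0.58, a call lost with total reads only (0 higher and 8 lower). The only endosperm marker of 3 to be called was NCED6, which rose (camera adjusted p = 0.394; 1 higher over the list alone; the median of the list turned to -0.30 with total reads only). Of 12 seed coat markers 1 rose, 2 fell and 9 were not called, the same over the list alone (camera adjusted p = 0.533; 1 higher and 4 lower with total reads only).

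Largest changes are those among called genes with a symbol, at least 5 CPM in a group and replicates that did not overlap. Beyond the lists, the largest increases in the embryo included 3 stress or sugar genes and 1 regulator of indole glucosinolates. MYB34, that regulator, went from 2 reads to 9.82 ± 1.39 CPM, a ratio of 283 with a 95% counting interval from 77.9 to 2341. TRE1, the trehalase, rose from 0.465 ± 0.283 to 34.4 ± 5.67 CPM (log2 6.21), the ubiquitin ligase PUB19 from 0.871 ± 0.562 to 63.5 ± 15.5 CPM (log2 6.21) and MEE25, a predicted sugar epimerase, from 0.107 ± 0.0569 to 9.14 ± 0.263 CPM (log2 6.33). The largest decreases were in TGG1, the myrosinase that cleaves glucosinolates (54.2 ± 7.18 to 0.400 ± 0.255 CPM, log2 -7.05), the mechanosensitive channel MSL9 (7.69 ± 2.67 CPM to 0 reads, at least 42.4-fold lower), PYL4, the leaf polarity regulator ZPR3 (log2 -4.68), the haemoglobin HB2 (log2 -4.20) and the homeobox factor HB33 (log2 -4.16).

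**Figure D2:**
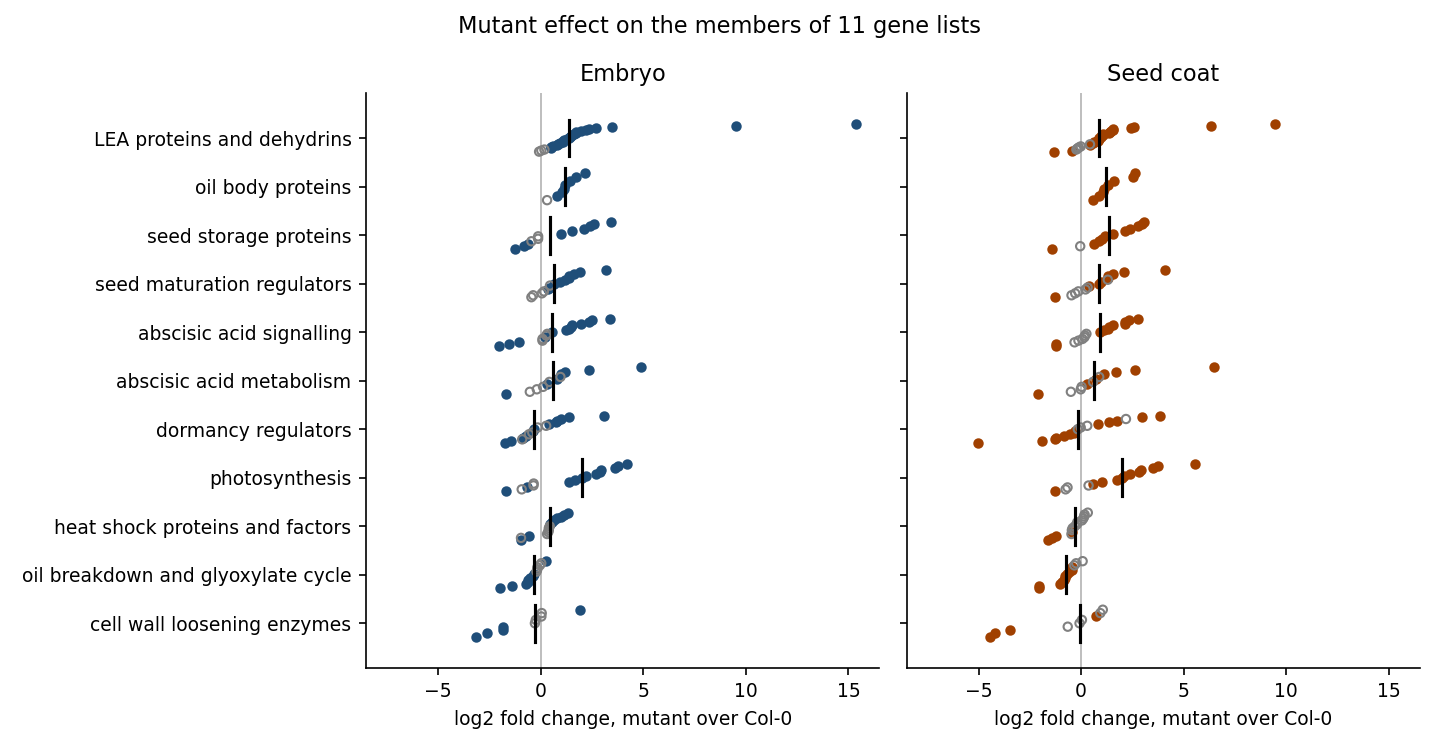
Log2 fold change of mutant over Col-0 for each tested member of 11 gene lists, in the embryo and in the seed coat. Filled points were called at adjusted p under 0.05, open grey points were not, and the black bar is the median of the list; LEA proteins had a median of 2.63-fold in the embryo and 1.84-fold in the seed coat.

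In the mutant seed coat many of the same genes changed as in the embryo. DOG1 rose, as did 8 of 15 maturation regulators, 20 of 27 LEA proteins and dehydrins, 10 of 12 storage proteins and 9 of 17 abscisic acid signalling genes, and 11 of 14 oil breakdown genes fell. Camera called these lists with the preset correlation and lost each with an estimated correlation (adjusted p = 0.288). No heat shock gene of the list rose. In total 4035 genes rose and 3819 fell, 7854 or 48.4% of those tested, with 1842 higher and 1304 lower by at least 2-fold. Scaled by total reads only, 2413 rose and 6189 fell. Replicates did not overlap for 55.5% of genes, beside 10% by chance.

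DOG1 rose from 25.9 ± 9.46 to 374 ± 37.0 CPM in the seed coat (log2 3.86). Dormancy regulators split into 5 higher, 8 lower and 4 not called (camera adjusted p = 0.815; 6 higher and 8 lower over the list alone). TCP14, which promotes germination, was 1 of the 5 that rose (1.21 ± 0.0660 to 9.43 ± 1.45 CPM, log2 2.94). Seed maturation regulators had 8 higher, 1 lower and 6 not called (camera adjusted p = 0.0244; adjusted p = 0.288 with an estimated correlation; 8 higher and 1 lower over the list alone), a call lost without the first mutant seed coat library (adjusted p = 0.0502). ABI3 rose from 121 ± 10.9 to 299 ± 25.0 CPM (log2 1.30) and FUS3 from 35.5 ± 7.97 to 105 ± 25.5 CPM (log2 1.56), and the MADS factor AGL15 fell (log2 -1.26). Repressors of the maturation program had 2 higher, 5 lower and 5 not called, the same over the list alone (camera adjusted p = 0.512; its median of 0.00 turned to -0.29 with total reads only). HSI2 fell with log2 -0.71 and its relative VAL3 rose with log2 2.57.

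Storage proteins rose in 10 of 12 members, with 1 lower and 1 not called, the same over the list alone (camera adjusted p = 0.000324; adjusted p = 0.288 with an estimated correlation). SESA1 went from 104 ± 43.3 to 852 ± 40.5 CPM (log2 3.04) and the cruciferin CRA1 from 3549 ± 531 to 8043 ± 1118 CPM (log2 1.18), whereas the albumin SESA4 fell (log2 -1.41). All 8 oil body proteins rose, also over the list alone (camera adjusted p = 9.7e-05; adjusted p = 0.288 with an estimated correlation), among them OLEO1 (log2 1.59) and the caleosin ATS1 (log2 2.62). LEA proteins and dehydrins had 20 higher, 2 lower and 5 not called, the same over the list alone (camera adjusted p = 5.24e-05; adjusted p = 0.288 with an estimated correlation; 19 higher and 5 lower with total reads only). ERD10 rose from 1.14 ± 0.356 to 817 ± 85.8 CPM (log2 9.43) and COR47 from 0.355 ± 0.333 to 32.7 ± 6.52 CPM (log2 6.35). EM1 and GEA6 (EM6), the classical targets of ABI5 in the drying seed, fell (log2 -1.34 and -0.44). With RLE size factors only 1 gene of the list was called lower.

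Abscisic acid signalling rose in 9 of 17 members, with 2 lower and 6 not called (camera adjusted p = 0.0185; adjusted p = 0.288 with an estimated correlation; 10 higher and 2 lower over the list alone). The kinase OST1 rose from 11.3 ± 3.81 to 78.0 ± 5.74 CPM (log2 2.79) and HAI3 with log2 2.12, while PYR1 (log2 -1.22) and ABI1 (log2 -1.23) fell. Abscisic acid metabolism had 6 higher, 1 lower and 5 not called, the same over the list alone (camera adjusted p = 0.129), with the oxidase AAO3 higher (log2 1.10) and NCED5 lower (log2 -2.10). Gibberellin metabolism and signalling had 7 higher, 2 lower and 7 not called, the same over the list alone (camera adjusted p = 0.173; its median turned to -0.04 with total reads only). GA2, an early synthesis enzyme, rose with log2 2.19, as did RGL2, a repressor of germination (log2 0.93).

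Photosynthesis genes rose in 11 of 15 members, with 1 lower and 3 not called (camera adjusted p = 0.000268; adjusted p = 0.288 with an estimated correlation; 11 higher and 2 lower over the list alone). RCA rose from 3.70 ± 0.213 to 172 ± 14.3 CPM (log2 5.53) and GAPA, a Calvin cycle enzyme, fell (log2 -1.27). Oil breakdown and the glyoxylate cycle fell in 11 of 14 members, 0 rose and 3 were not called (camera adjusted p = 1.74e-05; adjusted p = 0.288 with an estimated correlation; 12 lower over the list alone). PCK1 went from 1248 ± 115 to 305 ± 26.9 CPM (log2 -2.04) and the malate synthase MLS fell with log2 -0.96, while the isocitrate lyase ICL was not called (log2 -0.33). Fatty acid and oil synthesis had 4 higher, 7 lower and 4 not called, the same over the list alone (camera adjusted p = 0.512). The 3 raffinose family genes rose, also over the list alone (camera adjusted p = 0.0709), with GolS2 at log2 1.27. Heat shock proteins and factors had 0 higher, 4 lower and 11 not called, the same over the list alone (camera adjusted p = 0.173; 10 lower with total reads only), and AT1G53540, a small heat shock protein, was lower (log2 -0.47). Cell wall loosening enzymes had 1 higher, 3 lower and 5 not called, the same over the list alone (camera adjusted p = 0.182). DNA replication genes had 2 lower and 5 not called (camera adjusted p = 0.29; 1 lower over the list alone). Embryo markers had 1 higher, 3 lower and 7 not called, the same over the list alone (camera adjusted p = 0.455; the median turned to -0.26 with total reads only). Endosperm markers had 2 higher and 1 not called (camera adjusted p = 0.149) and seed coat markers 5 higher and 7 not called (camera adjusted p = 0.0973), both unchanged over the list alone. With total reads only these counts were 1 higher for endosperm markers and 1 higher and 1 lower for seed coat markers. TT5, a flavonoid enzyme, rose with log2 3.21.

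By the same naming rule, the largest increases in the seed coat besides ERD10 and COR47 were in BOR4, ABCC13, ENODL18 and MYB34. BOR4, a borate exporter, went from 3 reads to 18.0 ± 4.56 CPM, a ratio of 226 with a 95% counting interval from 77.0 to 1099, and ABCC13, a transporter, from 2 reads to 8.16 ± 0.995 CPM, a ratio of 153 with an interval from 42.1 to 1273. ENODL18, an early nodulin-like protein, went from 3 reads to 7.34 ± 0.781 CPM, a ratio of 92.9 with an interval from 31.4 to 453, and MYB34 rose with log2 6.70. The largest decreases were in BGLU4, a beta-glucosidase (7.01 ± 2.38 CPM to 0 reads, at least 26.0-fold lower), the purine permease PUP7 (14.2 ± 5.03 to 0.422 ± 0.420 CPM, log2 -5.06), the glutaredoxin GRX480 (log2 -5.01), PYL4 (31.6 ± 20.2 to 0.973 ± 1.03 CPM), the jasmonate enzyme OPR3 (log2 -4.89) and the ferredoxin reductase RFNR2 (log2 -4.76).

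**Figure D3:**
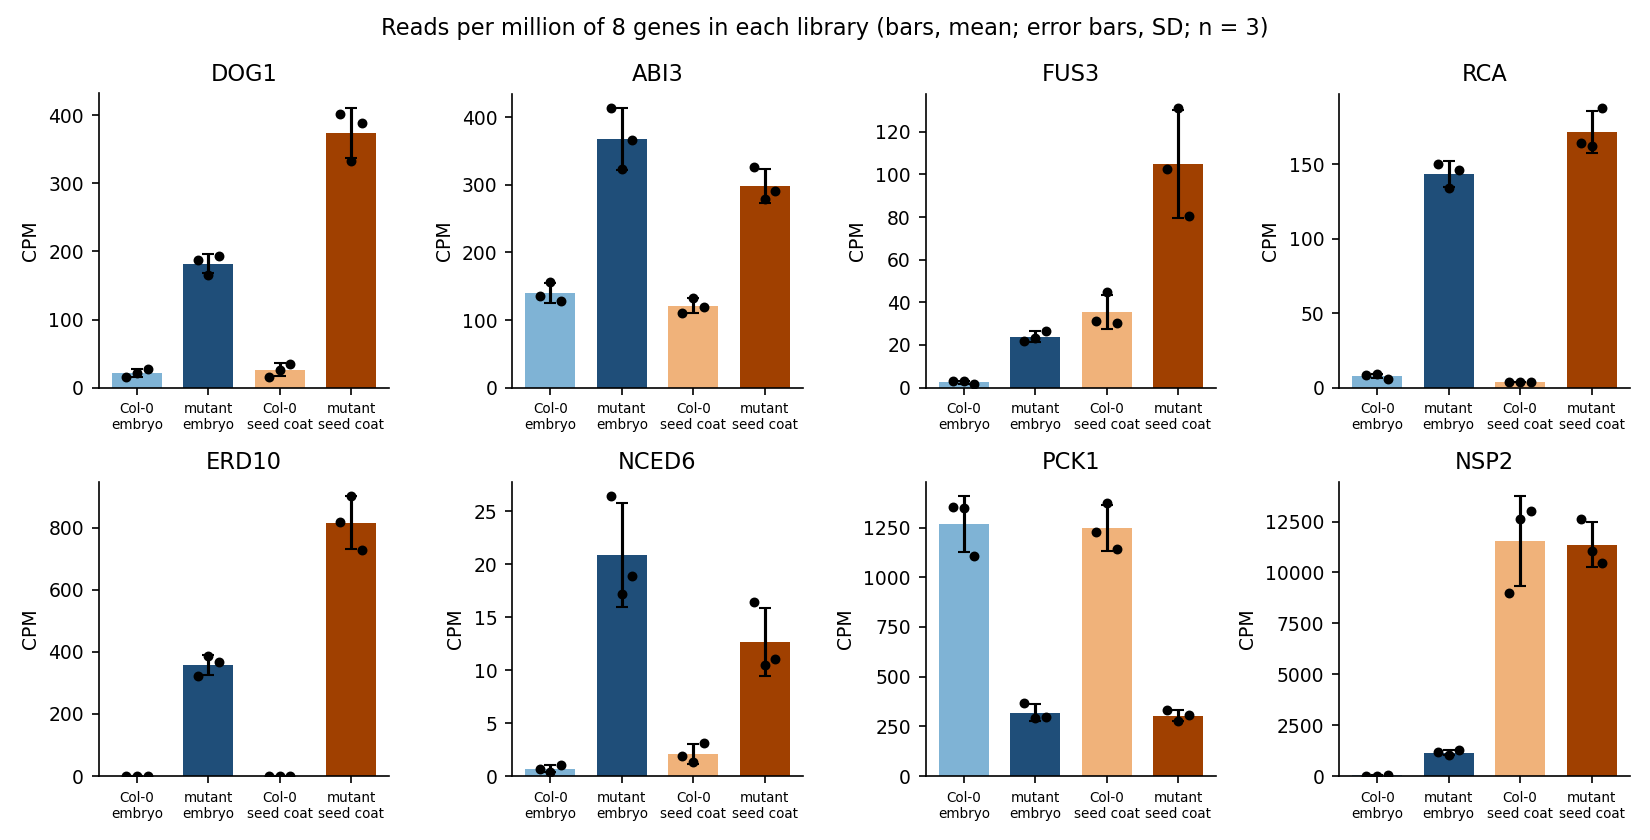
Expression in CPM of 8 genes, DOG1, ABI3, FUS3, RCA, ERD10, NCED6, PCK1 and NSP2, in the 4 groups. Points are single libraries, bars are means and error bars are SD (n = 3); DOG1 rose in both tissues and NSP2 rose in the embryo only.

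The genotype effects of the 2 tissues overlapped heavily. Of the genes tested, 2982 rose in both tissues and 2351 fell in both, 5333 in all where 1845 would be shared by independent lists, and 92 changed in opposite directions where independence gives 1836. Log2 fold changes of all genes correlated at r = 0.775 (rank correlation 0.759). Embryo and seed coat of the same number were taken to come from the same seed lot, so differences between lots can enter both comparisons. Independence is therefore not the value for unchanged genes, and how much the lots add to the overlap and the correlation was not tested. The shared genes include DOG1, ABI3, ERD10, RCA and OLEO1 among those that rose and PCK1, MFP2, PYR1 and PYL4 among those that fell. A further 2185 genes were called in the embryo only and 2429 in the seed coat only. The test of the difference between the tissues called 206 and 259 of these, in the fit that does not pair tissues of a seed lot. That fit recovered 26% of 2-fold differences in a simulation with few changed genes, a rate that need not hold here.

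Called differences of the mutant effect between the 2 tissues were fewer than the changes called in either tissue. The smallest p among the named genes belonged to NSP2, a glucosinolate gene that Col-0 expressed mainly in the seed coat. Of the lists, 4 of 27 LEA, 4 of 15 heat shock and 3 of 12 storage protein genes had a called difference. The list calls were lost with an estimated correlation (adjusted p = 0.511 for LEA and storage proteins and 0.394 for heat shock), and 20 of 60 splits of the libraries, the real one included, called at least as many lists. Those splits were drawn without regard to seed lots, and the others that reached the real 5 relabelled the 2 tissues unequally. Their contrast still held part of the genotype effect, so the count gives no value for unchanged libraries. The few splits that kept lots together called at most 3 lists. The test of the difference (seed coat effect minus embryo effect) called 932 genes, 328 with a higher and 604 with a lower effect in the seed coat, 223 and 252 of them by at least 2-fold. With embryo and seed coat of the same seed lot paired in the model, the count was 2579. It dropped to 476 without the first mutant embryo library, 563 without the last, 523 without the first mutant seed coat library and 518 without the last. NSP2, a nitrile specifier protein of glucosinolate breakdown, rose from 28.2 ± 9.17 to 1153 ± 126 CPM in the embryo and stayed at 11541 ± 2214 and 11371 ± 1127 CPM in the seed coat (difference log2 -5.38, adjusted p = 4.2e-06). UGT71B6, which couples abscisic acid to glucose, rose in the embryo only (0.332 ± 0.00823 to 4.50 ± 0.222 CPM; difference log2 -3.47). BRU6, an auxin-conjugating GH3 enzyme, fell in the seed coat (259 ± 40.9 to 52.3 ± 8.86 CPM) and rose in the embryo (difference log2 -2.89), and the mitochondrial dehydrogenase NDA1 rose more in the embryo (difference log2 -1.97). In the other direction, the cell wall enzyme XTH11 fell in the embryo (4.72 ± 0.514 to 0.768 ± 0.362 CPM) and rose in the seed coat (75.7 ± 3.26 to 159 ± 14.6 CPM; difference log2 3.66). The beta-glucosidase BGLU44 (difference log2 2.46), TCP14 (2.21) and the basic helix-loop-helix factor LRL1 (1.41) also had the higher effect in the seed coat.

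By list, the seed coat effect was higher for storage proteins, with 3 higher, 0 lower and 9 not called (5 and 1 over the list alone; 5 and 0 with total reads only; camera adjusted p = 0.000688; adjusted p = 0.511 with an estimated correlation), PAP85 differing by log2 1.62. Seed coat markers had 2 higher and 10 not called, the same over the list alone (camera adjusted p = 0.00148; adjusted p = 0.394 with an estimated correlation), with GL2, a trichome and mucilage factor, at log2 2.82. The seed coat effect was lower for LEA proteins and dehydrins, 4 lower and 23 not called (6 over the list alone; camera adjusted p = 1.64e-05; adjusted p = 0.511 with an estimated correlation), LEA7 differing by log2 -2.41. Heat shock proteins and factors had 4 lower and 11 not called (8 over the list alone; camera adjusted p = 1.64e-05; adjusted p = 0.394 with an estimated correlation), with HSP70 at log2 -1.36. Oil breakdown had 4 lower and 10 not called (5 over the list alone; 2 with total reads only; camera adjusted p = 0.00126; adjusted p = 0.394 with an estimated correlation), with the thiolase PKT3 at log2 -0.83.

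**Figure D4:**
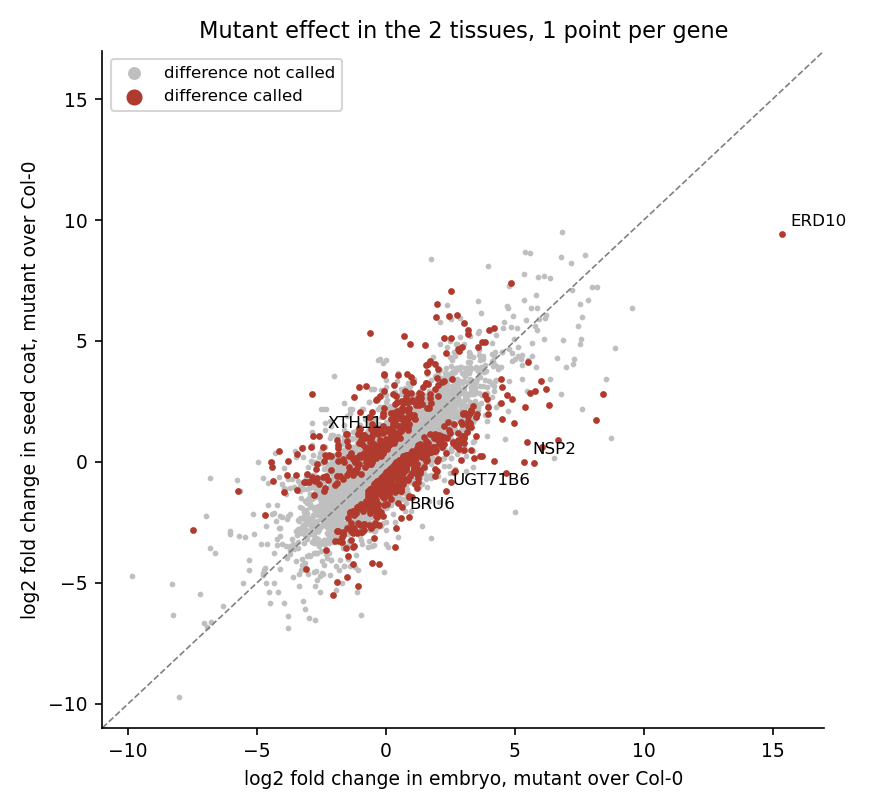
Log2 fold change of mutant over Col-0 in the embryo (horizontal) and in the seed coat (vertical) for each of the 16238 tested genes. Red points are the 932 genes whose effect differed between tissues, and most genes lie along the diagonal (r = 0.775).

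In Col-0 itself, most tested markers of the embryo and of the seed coat were higher in their own tissue: 10 of 11 embryo markers in the embryo and 7 of 12 seed coat markers in the seed coat. The endosperm gene EPR1 and the flavonoid genes TT4 and BAN were higher in the seed coat samples. In the embryo 5 of 12 storage protein and 5 of 15 photosynthesis genes were higher, list calls that were lost with an estimated correlation (adjusted p = 0.719 and 0.52). Here 3966 genes were higher in the seed coat and 3609 in the embryo, 7575 or 46.6%, with 1520 and 1615 of them by at least 2-fold, and replicates did not overlap for 55.7% of genes beside 10% by chance. With total reads only 1635 genes were higher in the seed coat and 8601 in the embryo. The medians of LEA proteins (to -0.03), abscisic acid metabolism and signalling, maturation regulators, the AITR and DIG family, cell wall enzymes, oil breakdown and heat shock genes turned negative under this scaling.

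EPR1, an extensin-like gene of the endosperm, was the most abundant transcript of the seed coat samples at 154346 ± 16850 CPM against 183 ± 12.5 CPM in the embryo (log2 9.72). CYP705A4, a cytochrome P450, had 0 reads in the embryo and 65.1 ± 0.276 CPM in the seed coat (at least 412-fold), the wax enzyme KCS5 was at least 95.4-fold higher and BAN, the tannin reductase, at least 57.6-fold. The cuticle transporter ABCG31 went from 1 read to 126 ± 19.0 CPM, a ratio of 7089 with a 95% counting interval from 1272 to 280046, and MLP31, a latex-like protein, from 3.14 ± 0.989 to 3881 ± 288 CPM (log2 10.26). In the embryo, TGG1 (log2 -5.98), the aquaporin PIP3 (log2 -5.93), HB33 (log2 -5.82) and the growth factor GRF5 (log2 -5.74) were higher.

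Embryo markers were lower in the seed coat in 10 of 11 cases, with 1 higher, the same over the list alone (camera adjusted p = 0.000102; adjusted p = 0.0277 with an estimated correlation); the exception was WOX2 (log2 0.82), not called higher with total reads only (0 higher and 10 lower). Seed coat markers had 7 higher, 1 lower and 4 not called, the same over the list alone (6 and 3 with total reads only; camera adjusted p = 0.00406; adjusted p = 0.323 with an estimated correlation), with the chalcone synthase TT4 at log2 6.37 and GL2 lower at log2 -1.83. Endosperm markers had 2 higher and 1 not called, the same over the list alone (camera adjusted p = 0.108). Storage proteins had 2 higher, 5 lower and 5 not called (2 and 6 over the list alone; 1 and 8 with total reads only; camera adjusted p = 0.028; adjusted p = 0.719 with an estimated correlation), with CRU2 at log2 -4.17 and SESA2 higher at log2 1.47. That call was lost without the first Col-0 seed coat library (adjusted p = 0.181) or the second Col-0 embryo library (0.065). Photosynthesis had 5 lower and 10 not called, the same over the list alone (11 lower with total reads only; camera adjusted p = 0.024; adjusted p = 0.52 with an estimated correlation), RBCS1A at log2 -2.75, and was lost without the second Col-0 embryo library (adjusted p = 0.0671). LEA proteins and dehydrins had 12 higher, 4 lower and 11 not called (13 and 5 over the list alone; 8 and 10 with total reads only; camera adjusted p = 0.108). FUS3 was higher in the seed coat (log2 3.77) and ABI4 in the embryo (log2 -5.70).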

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

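No test in this part was chosen after seeing the result, though some genes were named because they stood out in this very test. Of 100 named genes tested, 34 had an effect that differed between embryo and seed coat in the test of the difference of effect between tissues, 15 higher and 19 lower in the seed coat. Values are log2, seed coat effect minus embryo effect. Lower in the seed coat were ERD10 -5.96 (its size depends on the prior, since Col-0 embryo had 0 reads), NSP2 -5.38, MEE25 -4.00, UGT71B6 -3.47, RFNR2 -3.25, TRE1 -3.19, BRU6 -2.89, LEA7 -2.41, NCED6 -2.26, NDA1 -1.97, AT1G53540 -1.80, FUS3 -1.64, AT4G18660 -1.51, HSP70 -1.36, ABF2 -1.05, PKT3 -0.83, FAD2 -0.74, E12A11 -0.71 and MFP2 -0.68. Higher in the seed coat were SSI2 0.66, ATS1 0.91, ARA12 0.96, RCA 1.33, LRL1 1.41, EEL 1.68, BBM 2.15, TCP14 2.21, BGLU44 2.46, ZPR3 2.50, OST1 2.51, GL2 2.82, VAL3 2.97, XTH11 3.66 and ABCC13 4.53 (its size is uncertain, since Col-0 seed coat had few reads).

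Camera on the same difference called 5 lists, none of which stayed called with an estimated correlation (adjusted p = 0.511 for storage and LEA proteins, 0.394 for the others), with median log2 differences of 0.72 for storage proteins, -0.54 for LEA proteins and dehydrins, -0.19 for oil breakdown, -0.71 for heat shock proteins and 0.43 for seed coat markers.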

How the results depend on the processing

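Counts of calls moved with the threshold, the scaling, the seed lot block and the list test, and for the difference and the tissue lists also with single libraries. At a fold change of at least 2 the calls fell to 3004 (1730 higher, 1274 lower) in the embryo, 3146 (1842, 1304) in the seed coat, 475 (223, 252) for the difference and 3135 (1520, 1615) for tissue, and the overlap to 1901 (1226 higher, 675 lower). With total reads only, added after seeing the data, the embryo had 2296 higher and 6882 lower, the seed coat 2413 and 6189 and tissue 1635 and 8601. Libraries of the same number did not deviate together between genotypes (correlations of -0.30, -0.47 and -0.06 in the embryo and -0.19, -0.24 and -0.04 in the seed coat), so the genotypes share only a number. The replicate number as a block gave 7483, 7747, 881 and 7533 calls for embryo, seed coat, difference and tissue, and the seed lot block, also added after seeing the data, gave 2579 for the difference (835 higher, 1744 lower) and 9208 for tissue. No other count moved by over 1.5 times under either block. An estimated correlation called 0 lists in the embryo, 0 in the seed coat, 0 for the difference and 1 for tissue. Fry called 17 in the seed coat and 14 for tissue. Among these, fry called the dormancy regulators in the seed coat higher (adjusted p = 0.0258), where camera called no direction (adjusted p = 0.815). Leaving out 1 library gave 6320 to 7237 calls in the embryo, 6827 to 7382 in the seed coat, 6576 to 6967 for tissue, 476 to 844 for the difference (195 to 323 higher, 270 to 555 lower) and 4604 to 5167 for the overlap, and 9 to 12, 7 to 10, 5 to 6 and 2 to 5 lists for embryo, seed coat, difference and tissue. Without both mutant libraries numbered 2, added after seeing the data, the counts were 7641, 7689 and 777 for embryo, seed coat and difference. Of 164 named values 12 lost their call in at least 1 of the alternatives and 0 reversed; among them, in the seed coat, the log2 of MCM4 shrank to -0.59 without the second Col-0 library and that of MAN6 to -0.29 with unstranded counts. The cause was not tested.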

Other observations

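Ribosomal protein genes, which were not among the written lists, fell in both tissues of the mutant. Of 333 such genes, 188 fell and 18 rose in the embryo (median log2 -0.43, camera adjusted p = 4.68e-11; adjusted p = 0.747 with an estimated correlation), and 169 fell and 27 rose in the seed coat (median log2 -0.35, camera adjusted p = 1.69e-06; adjusted p = 0.97 with an estimated correlation). With total reads only the medians were -0.79 and -0.65, a scaling that shifted the median of all genes by -0.35 and -0.29. The 109 families of genes with the same product name were tested after the data were seen, following an earlier run that had split the ribosomal names into more families. In the seed coat 14 of 27 histone genes rose and 0 fell (camera adjusted p = 0.025; adjusted p = 0.97 with an estimated correlation), and in the embryo 16 of 23 HSP20-like chaperone genes rose and 1 fell (camera adjusted p = 0.0028; adjusted p = 0.701 with an estimated correlation).

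A few genes went from silence to clear expression or back. Besides ERD10, MSL9 and BGLU4, the phosphate transporter relative AT1G69480 had 0 reads in Col-0 seed coat and was at least 25.0-fold higher in the mutant. ERD10 and COR47 are neighbours in TAIR10.1, and the genes on either side of the pair, AT1G20430 and AT1G20460, were not called in the embryo (adjusted p = 0.117 and 0.909). Further along, AT1G20490 rose from 29 to 81 reads in the embryo (adjusted p = 0.00349) and also in the seed coat (adjusted p = 0.00692), where AT1G20460 rose too (adjusted p = 0.0247).

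For every pattern below, the tests were chosen after the result was seen. Close to 50% of the tested genes changed with genotype in each tissue. Scaling by total reads only did not remove this, since at least 75.9% of the calls kept their call and direction. That scaling moved all genes down, so decreases were nearly bound to be kept. Increases dropped from 4129 to 2296 in the embryo and from 4035 to 2413 in the seed coat. How far the calls depend on scaling therefore stays open. A trend with GC content or gene length does not account for the number of calls, since at least 92.3% were kept after each library's trend was removed. An earlier stage at collection could raise maturation genes, but only 50% of the called genes of fatty acid and oil synthesis, a program of earlier seed filling, were higher in the mutant embryo, so this stays open. Library measures also moved with genotype, and their bearing on the calls was not tested. Reads on no annotated exon of the counted strand, for example, stood at 3.53% in Col-0 embryo and 2.26% in mutant embryo.

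NSP2 and NCED6 were higher in the mutant embryo, although Col-0 expressed NSP2 mainly in the seed coat and NCED6 is usually read in the endosperm. Of 5 other genes at 1000 CPM or more in Col-0 seed coat and at least 100-fold lower in Col-0 embryo, 2 rose in the mutant embryo. Carry-over of seed coat material is still unlikely for NSP2. The change of these genes allows a median share of 0.0137% and at most 0.161% of such material, where NSP2 would need 9.89%. At that share EPR1 would stand at 19279 CPM in the mutant embryo, and it stood at 179 CPM. NCED6 would need a share of 159%, since the mutant embryo held more of it than the mutant seed coat sample. Carry-over of that sample as a whole cannot give this. The sample mixes seed coat and endosperm, so the share does not exclude carry-over of a part richer in NCED6. EPR1, an endosperm gene, stood at 183 CPM in Col-0 embryo and 179 CPM in mutant embryo. Reads of the paralogs NSP1, NSP3, NSP4 and NSP5 came to 10.03% of those on NSP2, too few to explain the rise of NSP2 by shared sequence.

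ERD10 and COR47 were nearly absent in Col-0 and present in the mutant. Cold during handling of the mutant seeds remains possible, since 5 of the 6 genes with enough reads to test, in a list of cold genes made after the result was seen, were higher in the mutant embryo and 3 in the mutant seed coat, RD29A with log2 3.01 in the embryo. Over all 11 genes of that list the share in the embryo is 45.5%, and CBF1 was not called. Of the genes not tested, COR15A and GOLS3 had 0 reads there, and CBF3 went from 2 reads in Col-0 to 0. COR15B went from 0 to 14 reads and KIN1 from 2 to 20. The list cannot tell cold from other causes of such a rise, so cold is left open. Reads lost to strand do not account for it, since ignoring strand gave 1 read on the pair in the 3 Col-0 embryo libraries. That count leaves out reads that overlap several genes, so it does not test loss to overlap. With the same gene models ERD10 had 17825 reads in the mutant embryo.

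Whether calls would arise under any grouping was weighed with tests that relabel the libraries. Of 10 splits of 6 libraries, 1 (the real one) reached the real count in the embryo (7610 genes), the seed coat (7854) and the Col-0 tissue comparison (7575), and the highest other count was 0 in each. With 10 splits the share cannot go under 0.1. Each other split also mixed the 2 real groups, so real differences became spread within groups. Few calls were thus likely from the start, and the 0 says nothing about calls among unchanged libraries. For the difference between tissues 2 of 60 splits reached 932 and the highest other count was 2068, from a split that relabelled 4 of 6 embryo libraries and left the seed coat labels real, so its contrast still held the genotype effect and it gives no value for unchanged libraries. A split and its mirror count as the same. The splits that relabelled 2 embryo libraries and left the seed coat labels real called 75, 24, 38, 56 and 26 genes. Those that relabelled 2 seed coat libraries and left the embryo labels real called 24, 20, 13 and 13. Splits that kept seed lots together gave 0. They and the partly relabelled splits also mixed the genotypes within groups, so these counts give no value for unchanged libraries. For the overlap 1 of 60 splits reached 5333 and the highest other count was 0, which decides nothing about its size, since a relabelled tissue had 0 calls to share. Camera called lists under other splits too: 8 beside the real 11 in the embryo (1 of 10 splits) and 8 beside 8 in the seed coat (2 of 10). For tissue it called 6 beside 4 (3 of 10) and for the difference 9 beside 5 (20 of 60). The splits with these counts still held part of the real genotype or tissue effect. They therefore cannot tell whether list calls with the preset correlation arise from genes that vary together. For the difference, splits that kept seed lots together called at most 3 lists, but such splits were few.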
